A study of Aspergillus niger with 6 samples.

How the data were processed

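RNA was measured by Illumina sequencing in mycelium of the filamentous fungus Aspergillus niger. The labels name 6 libraries, 3 of a strain that lacks rpnR and 3 of its control strain MA234.1, while the series' design text speaks of samples in duplicate. Per the labels' protocols, conidia were grown for 16 h at 30 °C and 200 rpm in 300 ml transformation medium with 1% glucose. The mycelium was then moved to 150 ml minimal medium with 25 mM xylose for 4 h at 250 rpm. RNA was extracted with TRIzol and purified on columns, and libraries followed Illumina's protocols.

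The submitters' processing notes name CASAVA 1.8.3, Trimmomatic, TopHat2, Cuffdiff 2.2.1 and Cufflinks, without saying which step each performed. The genome build and the gene models are not given in the sources used here. The deposited table holds 1 expression value per gene and strain and not per library. Its header calls it an expression value, and it is read here as the authors' FPKM (fragments scaled by transcript length and by mapped fragments) because Cuffdiff reports that unit. The values were fractional and reached 18598. They summed to 828095 in the control and 872090 in the deletion strain. The depth of the libraries is unknown, and no counting interval or floor was computed. The same table gives the authors' q-value for the comparison of the strains, the direction, a flag and annotations. The flag's rule (q of at most 0.05, a fold of at least 2 and 10 or more in 1 strain) was recomputed and differed in 0 rows.

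Because the table holds no value per library, no test between replicates and no standard deviation could be computed. The design fixed before the data were examined had a clause for this case, and it was followed: a gene was called changed when the authors' deposited q-value was under 0.05. Log2 ratios are those of the deletion strain over the control on the log2(FPKM + 1) scale, which understates the change of genes with low values, and folds are ratios of the deposited FPKM. Of 11910 genes, 2676 had a q of 1 and were taken as not tested by the authors (their highest value was 7.50 FPKM), which left 9234 tested genes.

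To adjust over a gene list alone, an upper bound of each unadjusted p-value was computed from the authors' deposited q-value, as q times its rank (ties at the highest rank) over 9234. The bound is exact only for the last gene of each group that shares a q, and 7568 tested genes shared theirs. That 99.4% of the bounds were whole multiples of 5e-05, within 0.02 of a step, checks the number of tested genes and not the single p-values. On simulated p-values for 9234 genes, 500 of them changed, 17.7% were given exactly and 100% of the bounds lay at or above the true value. Below 0.05 the bound was tight there: 754 genes by either value, and 2954 calls from either in lists of 50 genes adjusted alone. Those lists were drawn in equal parts from changed and unchanged genes. Lists with few changed genes were not simulated for this check of the bound. Of 200 random lists of 50 genes, 2.5% came under 0.05 in the test of calls and 3.5% in the test of direction. All of 50 lists lowered by 0.5 on the log2 scale were found by the test of direction. Lists of other sizes were not simulated, so this rate does not carry over to smaller lists, such as autophagy with 6 tested genes.

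Genes were assigned to 25 lists by text patterns over the file's gene names, KEGG product names, domain names and manual annotations. The patterns were written before the data were examined. Lists with fewer than 3 tested members were not tested, which left 23. For each, Fisher's exact test (two-sided) compared called with uncalled genes, and values above with values below the control, against all other tested genes. P-values were Benjamini-Hochberg adjusted over the 23 lists, separately for the tests of calls and of direction. The median log2 ratio was also placed among 10000 random lists of the same size, matched on mean FPKM in 20 bins. Genes of a list are not independent replicates, and 1 culture effect shared by co-regulated genes would move them together, so these p-values describe the deposited values. Classes, pathways and subgroups chosen after the data were seen are the 121 KEGG pathways with at least 5 tested genes, 68 classes of the file and 12 subgroups, each adjusted over its own family.

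Genes named in the text were chosen by a fixed rule. It took the targeted gene, the 12 called genes with the largest rise and the 12 with the largest fall among those with at least 5 FPKM in 1 strain, up to 3 called members of each list by absolute log2 ratio (for a list with none, the 2 with the highest mean), a set of known regulators and enzymes by symbol, and the 3 most abundant genes per strain. Of the regulators and enzymes in that set none could be matched, since the file gives a symbol to 8 genes only, hypA to hypH, and its protein numbers were not paired with the locus tags of the reference table. No coordinates are therefore given. Genes chosen otherwise are said to be. Alternatives tried were filters on mean FPKM, a minimum fold, a stricter q, centring of the log2 ratios, another pseudocount, and, added after the data were seen, the authors' flag, the removal of ribosomal protein genes and matching on GO terms. Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 was used.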

Results

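Gene expression was compared between an Aspergillus niger strain without rpnR and the control strain MA234.1, 4 h after mycelium grown on glucose was moved to xylose. The series describes rpnR as a predicted transcription factor gene regulated by FlbA, and its title places the gene in protein secretion and stress resistance. The deposited values are 1 authors' FPKM per gene and strain, made from libraries that the labels number 1 to 3 in each strain. No error or replicate number can therefore be attached to any value below. No row carried the symbol rpnR or the number in the sample titles, so the targeted gene is not analysed here and the strain labels were not checked through it.

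Genes for the cytosolic ribosome fell as a block in the deletion strain. Of 77 tested genes for ribosomal proteins of the eukaryotic type, 60 were called lower and none higher, and all 77 had lower values, with a median log2 ratio of -1.65. Genes for 2 arabinofuranosidases, a lipase and an antifungal protein rose, as did 5 of 15 genes of 1 secondary metabolism cluster, while chitinase and hydrophobin genes were among those that fell. No gene of the lists for folding in the endoplasmic reticulum, vesicle traffic, autophagy or starch breakdown was called. The test of calls did not set any of these lists apart from other genes, as only 6.54% of all tested genes were called.

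Of 9234 tested genes, 604 (6.54%) had a q under 0.05 in the authors' deposited table, 304 higher and 300 lower in the deletion strain. The median log2 ratio was 1.42 among the higher genes and -1.57 among the lower ones, against 0.02 over all tested genes. With the bound on the unadjusted p-value, 1670 genes came under 0.05, 853 higher and 817 lower. The lowest q in the authors' deposited table was 0.0027, shared by 171 genes. At q under 0.01 the count was 239.

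**Figure D1:**
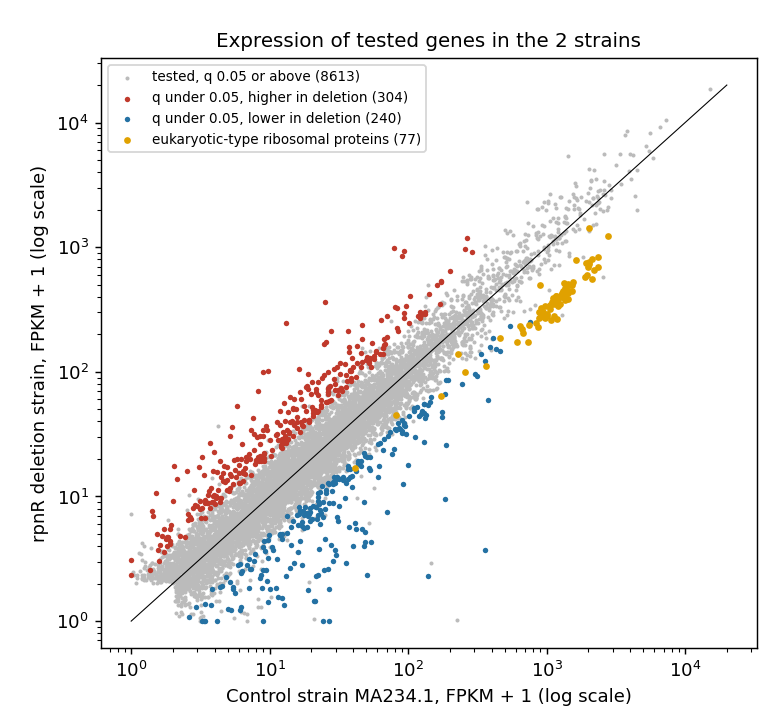
Each point is a tested gene, with the authors' FPKM + 1 in the control strain on the horizontal and in the rpnR deletion strain on the vertical axis, both logarithmic; the line marks equal values. The 77 eukaryotic-type ribosomal protein genes, of which 60 were called, lie below the line; 304 other called genes lie above it and 240 below.

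On the log2(FPKM + 1) scale, the largest rise among called genes with at least 5 FPKM in 1 strain was that of protein 1145520, a secreted lipase by its annotation, from 12.1 to 248 FPKM. Protein 1183897, small and secreted with an antifungal protein domain, rose from 88.6 to 852 FPKM. Among these 12 were 2 genes of the glycine cleavage system, glycine dehydrogenase (1161480, from 4.76 to 52.1 FPKM) and aminomethyltransferase (1098546, from 7.26 to 69.7 FPKM). The third tested gene of that system by product name, its H protein (1168765), named after its values were seen, was at 49.0 and 71.2 FPKM and was not called. A dapA-type synthase (1145855) rose from 26.6 to 211 FPKM, and a dienelactone hydrolase domain protein (1148466) from 8.80 to 100.4 FPKM. Protein 1019706, with no named domain, rose from 2.68 to 25.9 FPKM. Of the other 5, 4 belonged to secondary metabolism cluster 75 and 1 to cluster 73 (a cytochrome P450, 1112854, from 1.04 to 16.6 FPKM).

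Ranked in the same way, the largest falls were those of 1142051, from 360 to 2.75 FPKM, and 1142053, from 139 to 1.30 FPKM, neither with a named domain. Protein 143825, annotated as SNU13 of the small nuclear ribonucleoprotein, and 1164382 were at 25.99 and 23.4 FPKM in the control and listed at 0 in the deletion strain. With a pseudocount of 0.1 these 2 came first, at log2 ratios of -8.03 and -7.87, ahead of 1142051 (-6.98) and 1142053 (-6.63). Other genes without a named domain fell: 180549 from 184 to 8.48 FPKM, 1166044 from 49.4 to 1.33 FPKM and 1136778 from 20.4 to 0.450 FPKM. Of 2 transporters of the major facilitator type, 1105147 fell from 46.7 to 3.02 FPKM and 1146101 from 25.8 to 0.826 FPKM. A TauD-type dioxygenase (1087288) fell from 53.2 to 3.31 FPKM, a cytochrome P450 (1154545) from 19.9 to 0.446 FPKM, and a hydrolase of cluster 49 (1092812) from 34.5 to 1.95 FPKM.

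**Figure D2:**
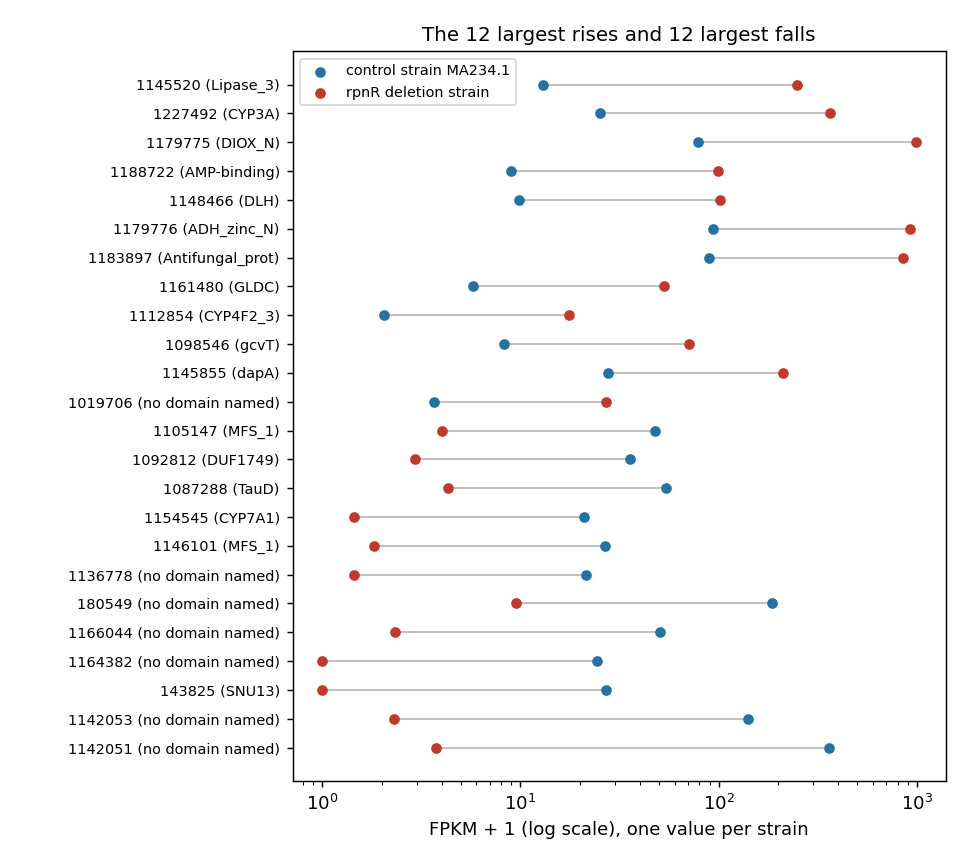
The 12 called genes with the largest rise and the 12 with the largest fall on the log2(FPKM + 1) scale, with the authors' FPKM + 1 in each strain on a logarithmic axis and a line joining the strains; labels give the protein number and the first annotation. The lipase 1145520 went from 12.1 to 248 FPKM, and 1142051 from 360 to 2.75 FPKM.

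The list fixed for the cytosolic ribosome, the machine that makes proteins, held 108 tested genes, of which 60 were called lower over all genes and 75 when adjusted over the list alone. The test of calls gave an adjusted p of 8.31e-42 and that of direction 2.22e-33 (Fisher's exact test, two-sided, adjusted over 23 lists). Its median log2 ratio of -1.53 lay below those of all 10000 expression-matched lists, whose median was 0.14. RPS10 (1148351) fell from 1189.9 to 262 FPKM, RPSA (1135824) from 732 to 171 FPKM and RPS15A (1142798) from 1069.8 to 260.1 FPKM. The list held 2 kinds of genes, separated after the values were seen. The 77 of the eukaryotic type took 11.4% of the summed FPKM in the control and 3.63% in the deletion strain. Large-subunit genes (45, median -1.67) and small-subunit genes (32, median -1.61) lay close together. The weakest member, named after its values were seen, was RPL10 (1143149), at 2009 and 1433 FPKM. The other 31 carry mitochondrial or bacterial ribosomal protein names. None of these was called, and all 31 values lay below the control, with a median of -0.39 (adjusted p of direction 4.75e-10 over 12 subgroups).

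**Figure D3:**
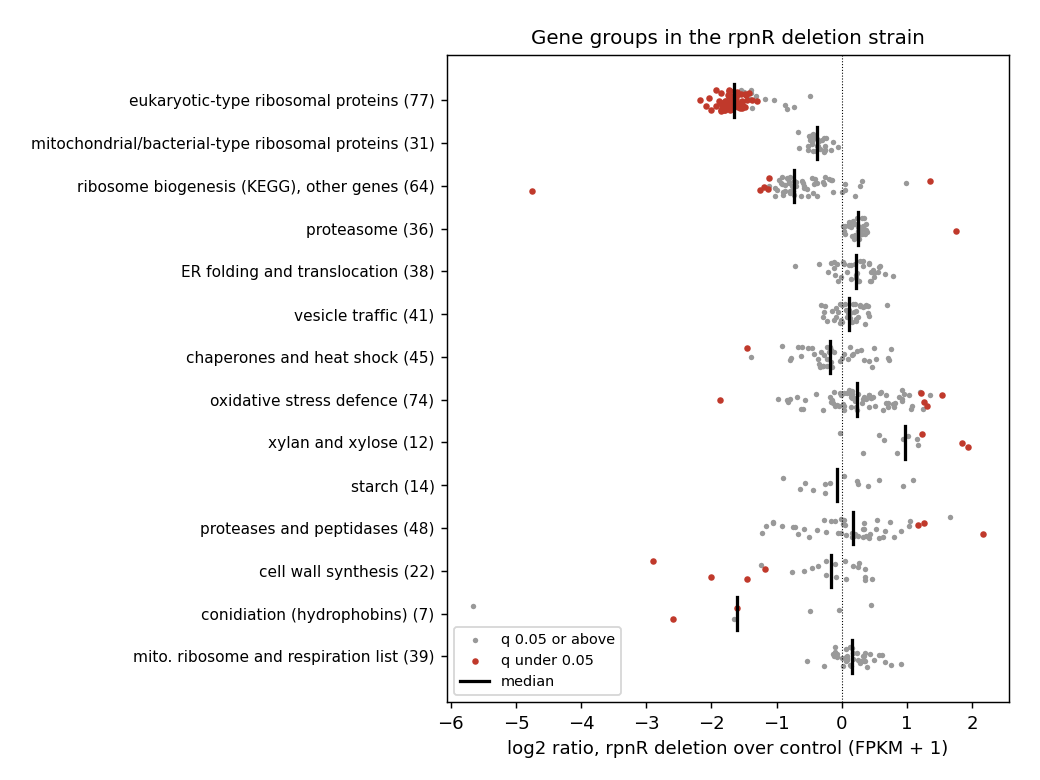
Log2 ratios of the deletion strain over the control, on the log2(FPKM + 1) scale, for the tested genes of each group (number in parentheses); red points have q under 0.05 and black bars are medians. The median was -1.65 for eukaryotic-type ribosomal proteins, 0.25 for the proteasome and 0.98 for the xylan and xylose list.

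Genes of the list for xylan and xylose, which release and use the sugar given to both strains, mostly lay higher in the deletion strain. Of 12 tested genes, 3 were called higher and none lower (5 higher when adjusted over the list alone), and 11 values lay above the control. The direction passed the test (adjusted p = 0.0187, Fisher's exact test), the number of calls did not (0.397), and the median log2 ratio of 0.98 exceeded all matched lists. The arabinofuranosidases 38549 and 1107655, which take arabinose off xylan side chains, rose from 41.6 to 161 and from 28.1 to 104 FPKM. A dehydrogenase of the D-xylose 1-dehydrogenase type (1164684) rose from 51.4 to 122 FPKM. Uncalled members, named after their values were seen, were xylose reductase (1156486) at 5538 and 8246 FPKM and a beta-xylosidase (1156695) at 3817 and 8547 FPKM. A GH11 endoxylanase domain protein (1101058) was not matched by this list. It was among the 3 most abundant genes in both strains, at 7330.3 and 10435 FPKM, and was not called. Of the 4 tested genes with GH10 or GH11 xylanase domains, a group formed after the values were seen, 2 lay above and 2 below the control and none was called (median log2 ratio -0.0028; percentile 44.1 among matched lists). The other 2 of the most abundant genes were 1188047, with no named domain, at 15064 and 18598 FPKM, and an isocitrate or methylisocitrate lyase (1145269) at 6559 and 9171 FPKM, neither called.

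Other enzymes of polysaccharide and protein breakdown showed few calls. In the list for cellulose and mannan, 1 beta-glucosidase rose and 1 fell among 26 genes (2 higher and 1 lower adjusted over the list alone): 1157877 from 0.817 to 2.998 FPKM and 1123700 from 16.0 to 1.83 FPKM. None of 14 starch genes was called by either adjustment, with glucoamylase (1166799) at 419 and 554 FPKM and an alpha-amylase (1099157) at 279 and 286 FPKM. Of 13 pectin genes, 1 fell, a pectate lyase domain protein (1107461) from 13.1 to 1.67 FPKM. Of 48 protease and peptidase genes, 3 rose and none fell, the same counts as adjusted over the list alone. They were 1105614 (from 2.33 to 13.98 FPKM), the subtilase 1158116 (from 8.08 to 19.5 FPKM) and 1173865 (from 117 to 282 FPKM), which by product name is an S-formylglutathione hydrolase and not a protease. None of these 4 lists passed the test of calls or of direction (adjusted p of direction 0.148 for cellulose, 1 for starch, 0.718 for pectin and 0.242 for proteases). Broader classes of the file, chosen after the values were seen, passed the test of direction but not that of calls. Of 138 genes with glycoside hydrolase domains, 9 rose and 6 fell, and 94 values lay above the control (median 0.28; adjusted p of direction 0.000941 over 68 classes). Of 315 MEROPS peptidase genes, 16 rose and 9 fell, and 199 lay above (median 0.14; 0.000363). By catalytic type, 11 of 131 serine peptidase genes rose and none fell (adjusted p of direction 0.00622, of calls 0.755). Of 89 metallopeptidase genes 3 rose and 2 fell, of 58 cysteine peptidase genes 2 rose and 5 fell, and of 14 aspartic peptidase genes none rose and 2 fell. None of 19 threonine peptidase genes was called, with 16 values above the control (adjusted p of direction 0.0393). Their overlap with the 14 proteasome core genes, all above the control, was not counted, so this result may repeat the proteasome shift described below.

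In the secretory pathway, none of 38 genes for folding and translocation in the endoplasmic reticulum was called by either adjustment, while 28 values lay above the control (median log2 ratio 0.22; adjusted p of direction 0.0184; percentile 97.9 among matched lists). Calnexin (1101772), a folding chaperone of glycoproteins, was at 520 and 710 FPKM, and CDC48 (1111182) at 396 and 480 FPKM. With GO terms matched as well, the direction of this list no longer passed Fisher's exact test (adjusted p = 0.853). KEGG pathways were looked at after the values were seen. In protein processing in the endoplasmic reticulum, 57 of 80 values lay above the control, and in N-glycan biosynthesis 26 of 33. Both passed Fisher's exact test of direction (adjusted p = 0.00170 and 0.00625 over 121 pathways), and no gene of either was called. Protein export (9 of 17 above), various types of N-glycan (18 of 33) and GPI anchors (6 of 23) did not pass. Overlap with the list was not counted. None of 41 vesicle traffic genes was called, with VAMP4 (1143204) at 281 and 307 FPKM and SEC23 (1083022) at 150.02 and 181 FPKM. None of 6 autophagy genes was called, with ATG3 (1186552) at 56.3 and 67.8 FPKM and 1179463 at 47.2 and 50.7 FPKM. The adjusted p of direction was 0.148 for vesicle traffic and 0.0725 for autophagy.

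All 36 proteasome genes had values above the control (adjusted p of direction 4.50e-10), by a median log2 ratio of only 0.25, and 1 was called. That gene, an RPT2-type ATPase (1187592), rose from 3.57 to 14.4 FPKM. The proteasome's median stood at percentile 97.1 of expression-matched lists. In the ubiquitin list of 52 genes, 2 were called lower: RPS27A (1135631), a ubiquitin fused to a ribosomal protein, from 2131 to 559.8 FPKM, and a USP7-type hydrolase (1185781) from 22.0 to 9.82 FPKM. Of 46 DNA repair genes, 1 rose, a cryptochrome (1091657, from 0.717 to 2.58 FPKM), and the 1 that fell was the same RPS27A gene. Neither list passed either test, and adjusted over each list alone the counts were the same.

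Among stress genes, 30 of 45 chaperone values lay below the control (median log2 ratio -0.18; adjusted p of direction 0.0428; percentile 0.41). Only an HSP12-type gene (1189150) was called, falling from 128 to 46.2 FPKM. The direction of this list did not pass Fisher's exact test when log2 ratios were centred (adjusted p = 0.0811) or members held to a mean of 5 FPKM (0.0809). In the list for oxidative stress defence, 4 of 74 genes rose and 1 fell, and 53 values lay above the control (median 0.24; adjusted p of direction 0.00237; percentile 99.8). Glutathione S-transferases 1028120 and 1021683 rose from 91.98 to 268 and from 121 to 299.5 FPKM, and a thioredoxin (1143747) fell from 175 to 47.0 FPKM. Adjusted over the list alone, the counts of both lists were the same.

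Genes of the fungal wall and surface fell in part. Of 22 cell wall genes, 4 fell and none rose (5 lower adjusted over the list alone), and the list passed neither test (adjusted p of calls 0.397). The 3 with the largest change were chitinases, enzymes that cut chitin: 1129677 fell from 10.5 to 0.547 FPKM, 1165650 from 4.00 to 0.241 FPKM and 1158625 from 16.1 to 5.22 FPKM. The list for conidiation matched hydrophobins, small surface proteins, and no regulator of spore formation. Of its 7 tested genes 2 fell (4 adjusted over the list alone), 6 had lower values, and the median log2 ratio of -1.61 lay below all matched lists (adjusted p of direction 0.133, Fisher's exact test). The gene hypB fell from 10.04 to 0.843 FPKM and hypC from 18.5 to 5.39 FPKM. The other genes with a symbol were named outside the rule. In the authors' deposited table hypF, at 146 and 1.91 FPKM, had a q of 0.0564 and hypH, at 20.2 and 5.69 FPKM, a q of 0.0665. The genes hypD (19.6 and 13.6 FPKM), hypE (14.4 and 13.8 FPKM) and hypG (0.604 and 1.18 FPKM) were not called, and hypA was not tested.

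Cytochrome P450 genes, whose products oxidise varied substrates, had 5 rises and 2 falls among 76 (5 and 3 adjusted over the list alone), with 51 values above the control (median 0.17; percentile 99.05; adjusted p of direction 0.0184, and 0.0508 for members with a mean of at least 5 FPKM). The P450 gene 1227492 rose from 24.2 to 362 FPKM. Of 351 Zn2Cys6 transcription factor genes, 16 rose and 2 fell, and 220 values lay above the control (median 0.14; adjusted p of direction 9.62e-05; adjusted p of calls 0.765). The leading ones were 1161008 (from 4.50 to 18.7 FPKM), 1082437 (from 4.83 to 18.9 FPKM) and 1161571 (from 3.24 to 10.2 FPKM). Counts adjusted over that list alone were the same. The file's own class of 480 transcription factor genes, chosen after the values were seen, also had 16 rises and 2 falls. It had 270 values above the control and passed neither test (adjusted p of direction 0.170 and of calls 0.0762 over 68 classes).

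The list fixed for the mitochondrial ribosome and respiration matched 39 tested genes, all for respiratory chain subunits or their assembly. Of these, 30 values lay above the control and none was called (median 0.16, at percentile 77.9 of expression-matched lists; adjusted p of direction 0.00548, and 0.0509 with GO terms matched). Its most abundant members were subunits of succinate dehydrogenase, 1142789 at 790.2 and 1478 FPKM and 1143907 at 863 and 1322 FPKM. In the list for ergosterol and fatty acid synthesis, 3 of 56 genes fell. They were the P450 1154545 and 2 fatty acid synthase subunits, 1130281 (from 5.16 to 0.291 FPKM) and 1080257 (from 1.61 to 0.0718 FPKM), which the file places in secondary metabolism cluster 2. The KEGG pathway of fatty acid biosynthesis, looked at after the values were seen, had 11 rises and 3 falls among 58 genes (adjusted p of calls 0.000628 and of direction 3.84e-06 over 121 pathways). Of these, 38 carry a fabG-type reductase name, and the other 20 had 2 rises and 2 falls (adjusted p of calls 0.0651 and of direction 0.0163 over 12 subgroups). The pathway of unsaturated fatty acids had 10 rises and 1 fall among 53 genes (adjusted p of calls 0.00632 and of direction 0.000920). How many of these 53 carry a fabG-type name was not counted, so the 2 pathways cannot be taken as independent results. Of 12 genes matched by the patterns for iron, 1155382 rose from 34.6 to 74.6 FPKM and a ferric reductase domain protein (1157566) fell from 1.94 to 0.303 FPKM. By name 1155382 is an NADPH oxidase and not a gene of iron uptake. None of 12 nitrogen genes was called, with nitrite reductase (1188839) at 1202 and 1565 FPKM and urate oxidase (1144686) at 331 and 478 FPKM. None of 4 secondary metabolism backbone genes matched by the fixed patterns was called, with 1125793 at 15.2 and 14.9 FPKM and 1155978 at 5.53 and 6.36 FPKM. In the file's own class of backbone enzymes, chosen after the values were seen, 3 of 41 genes rose and 6 fell, more calls than among other genes (adjusted p of calls 0.0148 over 68 classes; of direction 1). The last 4 fixed lists passed neither test, adjusted over each list alone their counts were the same, and those for sugar transport (0 tested genes) and multidrug transport (1) were not tested.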

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

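The authors' flag, the removal of the ribosomal protein genes and matching on GO terms were chosen after the data were seen; the other alternatives were planned. No paired analysis was possible because the table holds 1 value per strain and no value per library. For the same reason leaving out libraries, the replicate block, limma with or without its trend, camera, fry and other splits of the samples were not run, and nothing can be said of a single library's weight. The count of 604 changed genes was 601 and 529 with a mean FPKM of at least 1 and 5, 595 with a minimum fold of 2, 504 by the authors' flag and 544 without ribosomal protein genes. At q under 0.01 it was 239, with 112 of 304 higher and 127 of 300 lower genes, through the stricter threshold itself. Centring moved every log2 ratio by the median of 0.02 and changed no called direction, and the pseudocount does not enter q. A pseudocount cannot turn a gene's direction, but it moves sizes and order. In a comparison added after the data were seen, with 0.1 in place of 1, 8 of the 12 largest rises and 9 of the 12 largest falls stayed, and with 5, 10 and 7, since small pseudocounts favour genes near 0.

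Of 111 list values under alternatives, 101 kept their direction and side of the threshold (centring cannot move calls made on q and is counted for direction only). The direction of chaperones no longer passed Fisher's exact test with members of at least 5 FPKM (median -0.18, adjusted p = 0.0809) or with centring (-0.20, 0.0811), that of P450 genes with members of at least 5 FPKM (0.16, 0.0508), and those of folding in the endoplasmic reticulum (0.032, 0.853) and mitochondrial ribosome and respiration (0.12, 0.0509) with GO terms matched. The hydrophobins' direction passed with members of at least 5 FPKM (-1.63, 0.0367). Medians of 4 lists that never passed changed sign: starch (0.034), pectin (-0.29) and nitrogen uptake (-0.036) with members of at least 5 FPKM, and DNA repair (0.016) with GO terms matched. Beyond the changed membership, the cause was not tested. Depth is unknown, so it cannot be said which low genes were out of reach.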

Other observations

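The classes, pathways and subgroups below, the genes named from them, and the tests of library scaling, of the shared direction of proteasome genes and of the near-0 genes, were chosen after the data were seen. Genes of predicted secondary metabolism clusters were called more often than others: of 419, 30 rose and 23 fell (adjusted p of calls 0.000126 over 68 classes, Fisher's exact test). In cluster 75, 5 of 15 genes rose: its hybrid polyketide and peptide synthase (1188722) from 7.93 to 98.3 FPKM, a dioxygenase (1179775) from 77.7 to 991 FPKM, an alcohol dehydrogenase (1179776) from 92.8 to 923 FPKM, the P450 1227492 and a transporter (1155139) from 15.4 to 105 FPKM. The 1 gene of that cluster that fell, 1168731, carries the ribosomal protein name RPL10A. In cluster 49, 5 of 16 genes fell and none rose, its peptide synthetase (1186498) from 8.74 to 0.425 FPKM. In cluster 2, 7 of 19 fell and 1 rose, among the falls both fatty acid synthase subunits. The 3 clusters passed Fisher's exact test of calls (adjusted p = 0.00390, 0.0318 and 0.000287) but not that of direction (0.608, 0.625 and 0.801), as did the chitinase domain family, with 4 of 11 genes lower (0.0401).

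Of 57 genes of the KEGG pathway for valine, leucine and isoleucine degradation, 15 rose and 3 fell (adjusted p of calls 6.32e-07 over 121 pathways), with 3-hydroxyisobutyrate dehydrogenase (1113924) rising from 16.8 to 52.6 FPKM and methylglutaconyl-CoA hydratase (1106429) from 11.6 to 31.6 FPKM. The pathway for synthesis of the same amino acids did not pass (2 of 25 genes higher and 3 lower, adjusted p of calls 0.110 and of direction 0.481). Its called genes were mixed: both 2-isopropylmalate synthase genes fell, 1114520 from 48.0 to 3.31 FPKM and 1102323 from 109 to 50.5 FPKM. A branched-chain aminotransferase (1148631) fell from 40.2 to 5.10 FPKM, while a 3-isopropylmalate dehydrogenase (1223020) rose from 13.6 to 49.5 FPKM and a dihydroxy-acid dehydratase (1128692) from 34.6 to 92.5 FPKM. Among 22 genes picked by product name, 2 rose and 3 fell (adjusted p of direction 0.241, of calls 0.0245 over 12 subgroups). In the lysine synthesis pathway (3 of 24 genes higher and 4 lower, adjusted p of calls 0.00647, of direction 0.356) homocitrate synthase (1126600) fell from 112 to 29.3 FPKM and 2 LYS2-type genes fell, while the 3 genes that rose were all dapA-type. Of 149 genes with short-chain dehydrogenase domains, 24 rose and 6 fell (adjusted p of calls 1.56e-06). Their overlap with the fabG-type reductases of the fatty acid pathways was not counted, so this cannot be taken as an independent result. The 716 genes with a predicted secretion signal had 33 rises and 29 falls and did not pass the test of calls (0.11).

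The first pattern weighed is the fall of the ribosomal protein genes: library scaling or a few abundant genes would move genes of the same level alike, and the ribosomal median lay 1.48 below the lowest of 10000 matched lists. A general loss of short transcripts would lower small secreted proteins too, which stood at percentile 41.1 of matched lists. Among the 33 ribosomal genes classed from general knowledge as long (15) or short (18), long minus short medians gave -0.043 (95% bootstrap interval -0.21 to 0.12). The interval lies below the 0.5 the explanation needs, which argues against it for these 33 genes. They are 42.9% of the 77, too few for a length check of the whole group. A lower ribosome-making programme as a whole may be involved: the 64 other genes of ribosome biogenesis had a median of -0.74, at percentile 0, with 5 called lower, 1 called higher and 57 values below the control. Adjusted over these 64 alone, 23 were called lower and 2 higher. Lower values also prevailed in the KEGG pathways for RNA transport (70 below the control, 8 above) and the spliceosome (69 below, 17 above). Their medians were -0.41 and -0.18, and their adjusted p of direction 1.08e-12 and 6.55e-08 over 121 pathways (Fisher's exact test). The pathways for RNA polymerase (20 below, 1 above) and aminoacyl-tRNA biosynthesis (33 below, 8 above) went the same way. Their adjusted p of direction was 9.50e-05 and 0.000371 (Fisher's exact test). Overlap with the biogenesis genes was not counted. A shift to lower values was thus not shown to be particular to ribosome making. Among these groups it was largest in the 77 eukaryotic-type genes (median -1.65), of which 60 were called lower. In RNA transport 8 of 78 genes were called lower and 1 higher, and in the spliceosome 1 of 86 each way. A difference in growth state between the cultures remains open. Where it goes with strain the design cannot separate it, and no value per library is held.

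The second is the small shift of the proteasome genes. A trend with expression level could account for part of its size: the matched lists had a median of 0.07 against 0.25 for the proteasome, which stood at percentile 97.1, just short of the bound set beforehand for excluding the trend. In matched lists of unrelated genes, the trend did not give the shared direction. Of 10000 such lists, 0 had every member above the control, with a median of 20 of 36 and a highest of 30. These lists lack the joint variation of 1 complex, so they cannot show what a trend acting on co-varying genes would give. That genes of 1 complex vary together from culture to culture remains open.

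The third is a transcription factor gene near 0 in the deletion strain. A C2H2 zinc finger gene (1140545) was at 225 FPKM in the control and 0.0190 FPKM in the deletion strain, and in the authors' deposited table its q was 0.528. One hypothesis is that it is the deleted gene. In all, 6 tested genes fell below 1% of a control value of at least 10 FPKM, and 2 of these carry a transcription factor domain. The second is 1162101 (19.9 and 0.0363 FPKM), so the deleted gene cannot be told apart between them. Both have the same q, which 14 tested genes share. Calls made on q thus missed both falls. Of 43 tested genes with an absolute log2 ratio over 3, 6 were not called. Why their q was high was not tested.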
